A study of Danio rerio with 8 samples.

How the data were processed

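Total RNA of whole zebrafish larvae was labelled with Cy3 and Cy5 and hybridised to an Agilent 2-colour expression array (design 026437, built on danRer7), per the labels' protocols and the file headers. On the first-orientation arrays Cy5 held E3 and Cy3 held PTZ RNA, and on the dye-swap arrays the reverse, per the labels. The authors deposited one scanner file per array, made with Feature Extraction 11.5.1.1 per the file headers, whose columns used here are linear intensities of each spot and its local background. They also hold a log10 ratio of Cy5 over Cy3 that Feature Extraction had background-subtracted and dye-normalized, per the file headers, which served as an alternative. A deposited value table was found to be the log2 ratio of the median Cy3 over the median Cy5 spot intensity, to within 5e-10 on every array, with no background subtraction, normalization or centring and with dye swaps not turned. Its column medians were -0.076, 0.21, 0.083 and 0.60 on the 30 min arrays (replicates 1 and 2, then their dye swaps) and 0.54, 0.58, 0.35 and 0.62 on the 90 min arrays. Its scale, centring and direction are thus known from the comparison with the scanner files.

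The analysis started from median spot and median background intensities, in place of the mean spot intensity that had been planned, since the files used here hold medians. Background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3, with control spots given no weight in the loess and left out afterwards. Between 3 and 29 outlier spots per array were left out. Ratios were turned to PTZ over E3 on every array and spots of one probe were averaged. A probe was tested if it was well above background on all 4 arrays in at least 1 of the 4 RNA groups. Files gave accessions but no gene names, so accessions were matched without versions to RefSeq transcripts of a later assembly (GRCz12tu), for names and not for coordinates. Of 43603 probes, 25978 matched a symbol and 17625 did not. A gene with several probes was represented by that with the highest mean intensity, and unnamed probes stood for themselves, which left 23929 features, 12171 of them with a symbol. Among 245 genes called at 90 min that had several probes, 239 had all probes of the same sign.

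The 2 arrays of a replicate, its first orientation and the dye swap of the same number, were averaged, and lmFit and eBayes were run on the 4 replicate values together, with 2 residual and 3.86 prior degrees of freedom. Contrasts were the mean ratio at 30 min, the mean ratio at 90 min and their difference, each adjusted by Benjamini-Hochberg at 0.05. Gene-specific dye effects had an SD of 0.14 to 0.18 against 0.14 to 0.27 for the replicate ratios, and cancel in the mean of both orientations. The array of first orientation and its dye swap correlated at -0.21 and 0.094 in the 30 min replicates and at 0.58 and 0.45 in the 90 min replicates. All arrays numbered 1 lay on one slide and all numbered 2 on another, scanned on another day and at another resolution, per the file headers, so the replicate number and the slide are one block, which was fitted as an alternative. That fit leaves 1 residual degree of freedom. A shift that a replicate shows at both durations is then not in the error of the 30 min or the 90 min mean. Deviations of same-numbered replicates from their duration means correlated at 0.28 across features, and same-numbered replicates share a slide, so the numbers were taken to pair the replicates. Where the blocked fit moves a count of calls by over 1.5 times or changes the call of a list, its value stands with the result.

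For 23 gene lists of pathways and cell types, members past the threshold were counted over all genes and adjusted over the list alone, and lists were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over lists. By fry, which asks whether the members move one way on balance and does not set them against other genes, 9 lists passed at 90 min, 0 at 30 min and 1 for the difference. The 9 were immediate early factors, unfolded protein response, glucocorticoid axis, inflammatory targets, neuropeptides, clock, p53 targets, cholesterol synthesis and skin. The 1 was the clock. Effectors (fry adjusted p = 0.0796), glycolysis (0.0553), photoreceptors (0.100), GABA (0.145), glutamate (0.162), blood (0.309) and liver markers (0.500) passed camera at 90 min but not fry. Of 802 list entries, 10 had no current symbol and 619 were measured. No list passed camera with an estimated correlation in any of the 3 comparisons, where the smallest unadjusted p was 0.0130 (cholesterol synthesis, difference). In that form camera refers its statistic to the 2 residual degrees of freedom, which leaves little room to pass. The clock list lost its call at 90 min although its estimated correlation (-0.030) lay below the preset 0.01. A lost call therefore does not by itself point to correlation between genes. The test, lists and naming rule were fixed before the data were examined, as were all alternatives but 3. By that rule the text names, per duration, the 10 largest rises and falls among genes with a standard symbol past the threshold and of one sign on all 4 arrays. Clone and locus names were replaced by the next gene. For the difference it names the 6 largest each way among those past the threshold whose replicates at 90 min both lie on one side of both at 30 min. Where too few passed, it names up to 5 each way with the smallest p. It adds up to 4 members per list past the threshold with the largest ratio, or the 2 with the smallest p at 90 min, and fosab, npas4a, egr1, bdnf, actb1 and eef1a1l1. It was applied to the blocked fit as well, after the unblocked result had been seen.

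The pipeline was tested on simulated arrays with 200 changed genes among 23929 features and spreads drawn from the fitted prior. Spreads were drawn independently of the size of a change, and a probe had the same dye effect on all arrays. In the data, fosab, npas4a and egr4, with high ratios at 30 min, had SDs of 1.43, 0.87 and 0.78 there. The rates below therefore hold for the simulated setting and do not give the power in these data. For the 90 min contrast 49 of 50 genes with a true log2 change of 1 and 9 of 50 with 0.5 were called, with 8 of 23729 unchanged features. At 30 min 19 of 25 genes with a change of 1 and 1 of 25 with 0.5 were called, and for the difference 15 of 25 and 0 of 25. The blocked fit was run on the same simulated arrays, which held no slide effect: 47 of 50 genes with a change of 1 and 1 of 50 with 0.5 were called at 90 min, 21 and 0 of 25 at 30 min, and 4 and 0 of 25 for the difference, with 9, 4 and 1 unchanged features. Each mean ratio rests on 2 biological replicates. Alternatives covered background correction, normalization, the deposited values, probe filters, the probe to gene rule, the treatment of dye swaps, the spread estimate, blocks, left-out replicates and thresholds. In the deposited values, which are not centred, the median of all features was -0.13 at 30 min and 0.16 for the difference, and list medians under that scaling were taken relative to it. Each gene whose ratio is given was well above background on at least 2 arrays of every group, so no ratio is given as a bound.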

Results

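Gene expression was measured in whole AB wild-type zebrafish larvae at 3 days post fertilization on 2-colour oligonucleotide microarrays with 43603 probes. PTZ is the usual abbreviation of pentylenetetrazole, a convulsant that blocks GABA-A receptors, and E3 is the salt medium in which zebrafish embryos are raised. For each duration, 20 larvae were held in 20 mM PTZ and 20 were moved to fresh E3, for 30 or 90 min, and the paired RNAs were hybridised to one array. Each duration had 2 biological replicates and its own E3 larvae, and each replicate was run on 2 arrays of opposite dye orientation. The 8 arrays therefore gave 4 replicate values of the PTZ over E3 ratio, 2 per duration. The labels state that the replicates were separate matings, and the arrays of each lay on a slide of their own. The p-values without a block thus measure the spread between 2 matings and slides together. Those of the blocked fit for a single duration leave out the part of that spread that both durations share. Between 32296 and 39189 probes per channel were well above background, and the median spot was 4.29 to 16.5 times its local background. Values are log2 ratios of PTZ over E3 as mean ± SD (n = 2 replicates) unless stated otherwise.

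The 90 min comparison asked which transcripts differed after the longer exposure. Among genes with a symbol, the largest rise was in npas4a, a neuronal activity-dependent transcription factor gene, at 4.44 ± 2.01 (SD, n = 2), a 21.7-fold mean. It was followed by fosab, the zebrafish c-fos gene, at 4.18 ± 1.61, and by the zinc finger factor gene egr4 at 3.08 ± 1.16. The kinase gene sik1 rose by 2.90 ± 1.04, the vitamin D 24-hydroxylase gene cyp24a1 by 2.86 ± 0.24, and junbb by 2.79 ± 0.40. The remaining genes of the largest 10 were ier2a (2.71), the growth factor binding protein gene igfbp1a (2.64), btg2 (2.57) and jdp2b (2.35). In all, 498 of 23929 tested features rose and 155 fell in limma at a Benjamini-Hochberg adjusted p under 0.05, of which 290 and 98 had a gene symbol (613 and 424 with the replicate block). At least a 2-fold change was seen in 124 of those that rose and 7 of those that fell, against 143 and 22 with the block. Adjusted p ranged from 0.00209 for cyp24a1 to 0.0325 for btg2 among these 10 genes, and each was higher in PTZ on all 4 arrays.

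Among genes with a symbol past the threshold and of one sign on all 4 arrays, the largest fall at 90 min was in serpinh1b, which encodes the collagen chaperone Hsp47, at -1.80 ± 0.47. Forkhead transcription factor genes made up 3 of the 10 largest falls, with foxc1a at -1.24 ± 0.17, foxd2 at -1.16 ± 0.21 and foxa2 at -0.96 ± 0.16. The 2 probes of foxd2 differed, at -1.16 and -0.41, and those of foxa2 were at -0.96 and -0.64. The basic helix-loop-helix gene bhlha9 fell by 1.13 on the log2 scale and the general transcription factor gene taf11 by 1.13. The apelin receptor gene aplnrb (-0.90), the Wnt receptor gene fzd8a (-0.89), vgll4l (-0.85) and the paired box gene pax9 (-0.84) also fell. Their adjusted p lay between 0.00487 for foxc1a and 0.0332 for fzd8a.

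Of 35 measured immediate early transcription factor genes, 16 rose at 90 min, 0 fell and 19 did not pass. The list stood above other genes in camera with a preset correlation (adjusted p = 4.45e-17), a call that was lost (adjusted p = 0.223) with an estimated correlation. Adjusted over the list alone, 24 rose and 2 fell. Besides npas4a, fosab, egr4 and junbb, the stress factor gene atf3 rose by 2.099 ± 0.23. The list's median was 0.63 on slide 1 and 0.60 on slide 2, and with the replicate block 23 rose and 2 fell. Among activity-regulated effectors and MAPK feedback regulators, 15 of 36 rose and 0 fell, and 24 rose when adjusted over the list alone. Examples were sik1, btg2, gadd45ba (2.11 ± 0.40) and the MAPK phosphatase gene dusp1 (1.87 ± 0.73). The neurotrophin gene bdnf rose by 1.26 ± 0.37 (adjusted p = 0.0123). For this list camera gave an adjusted p = 1.25e-14, and adjusted p = 0.343 with an estimated correlation, with medians of 0.36 and 0.80 on slides 1 and 2, and 22 rose with the replicate block. The estimated correlation was 0.63 for effectors and 0.20 for immediate early factors, against the preset 0.01. The effector list did not pass fry (adjusted p = 0.0796). The ratio of egr1 was 0.48 ± 0.14 (adjusted p = 0.0466), but its E3 signal was well above background on 2 of 4 arrays and its PTZ signal on 3. Probes of one gene differed in size: the 3 probes of npas4a ranged from 0.82 to 4.44, and the 5 of fosab from 2.50 to 4.18.

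Of 24 cholesterol synthesis genes, 11 rose at 90 min and 0 fell, 18 rose when adjusted over the list alone, and none was lower than E3 on average. Camera gave an adjusted p = 6.01e-17, lost with an estimated correlation (adjusted p = 0.205), and the list's median was 0.45 and 0.41 on slides 1 and 2. The sterol oxidase gene msmo1 rose by 1.61 ± 0.35, the sterol sensor gene insig1 by 1.56 ± 0.43, ebp by 1.15 ± 0.23 and the squalene epoxidase gene sqlea by 0.96 ± 0.33. Circadian clock genes rose in 9 of 32 cases, and in 17 with 1 lower when adjusted over the list alone. They included the repressor genes bhlhe41 (1.36 ± 0.0019, E3 signal well above background on 3 of 4 arrays), cry1a (1.04 ± 0.42), bhlhe40 (0.96 ± 0.26) and per1b (0.93 ± 0.29). The clock list had a camera adjusted p = 6.06e-10, adjusted p = 0.205 with an estimated correlation, and medians of 0.26 and 0.24 on slides 1 and 2. With the replicate block 16 cholesterol genes and 14 clock genes rose.

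Stress-related lists also held genes that rose at 90 min. In the glucocorticoid and pituitary-interrenal list, 4 of 19 rose (9 adjusted over the list alone): the kinase gene sgk1 (1.54 ± 0.32), cisha (1.22 ± 0.13), the gluconeogenic gene pck1 (0.89 ± 0.19) and klf9 (0.78 ± 0.38). Among inflammatory cytokine and NF-kappaB target genes, 4 of 20 rose (11 adjusted over the list alone), namely socs3a (4.29-fold, SD 0.16 on the log2 scale), the gelatinase gene mmp9 (1.87 ± 0.17), ptgs2b (1.46 ± 0.29) and socs1a (1.43 ± 0.40). In the unfolded protein and integrated stress list, 8 of 29 rose (11, with 3 lower, adjusted over the list alone), led by trib3 (1.40 ± 0.19), chac1 (1.26 ± 0.17), ppp1r15a (1.05 ± 0.080) and ddit3 (0.85 ± 0.28). Camera's adjusted p for these lists was 1.10e-05, 5.88e-06 and 0.0261. In the same order they had an adjusted p = 0.223, an adjusted p = 0.223 and an adjusted p = 0.235 with an estimated correlation. Their medians were 0.35, 0.42 and 0.16 on slide 1, and 0.12, 0.25 and 0.034 on slide 2. With the replicate block 8, 11 and 10 rose.

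Heat shock and chaperone genes moved both ways at 90 min. Of 29 measured, 5 rose and 1 fell (7 and 4 adjusted over the list alone), with hspb9 at 1.68 ± 0.26, hsp70l at 1.48 ± 0.44 and hsp70.3 at 1.18 ± 0.23, and serpinh1b the one that fell. This list did not pass camera (adjusted p = 0.450), and its median (-0.020) and mean (0.093) differed in sign; with the replicate block 7 rose and 4 fell. Glycolysis and hypoxia genes rose in 7 of 42 cases (8 adjusted over the list alone). Those with the largest ratios were igfbp1a, igfbp1b (1.52 ± 0.37), the glycolytic regulator gene pfkfb3 (1.01 ± 0.070) and pdk2b (0.62 ± 0.22), so that the binding protein genes igfbp1a and igfbp1b, which are not glycolytic enzymes, led the list. Its camera adjusted p was 1.32e-05, with adjusted p = 0.235 with an estimated correlation, and its median went from 0.12 to -0.0032 relative to all genes under median centring in place of loess. Among p53 target and apoptosis genes, 2 of 24 rose (4 adjusted over the list alone), mcl1a (0.75 ± 0.12) and casp9 (0.53 ± 0.019), with a camera adjusted p = 0.0385 and adjusted p = 0.246 with an estimated correlation, and 3 rose with the replicate block. Slides 1 and 2 gave medians of 0.15 and 0.049 for the glycolysis list and 0.11 and 0.050 for the p53 list. None of 23 oxidative stress genes passed limma over all genes or over the list alone, and that list did not pass camera (adjusted p = 0.400). There gclm was at 0.33 ± 0.0053 (adjusted p = 0.0641, and 0.0327 with the replicate block) and nfe2l2a at 0.41 ± 0.50 (adjusted p = 0.263), and 1 oxidative stress gene rose in the blocked fit.

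Few genes of neuronal signalling passed the test at 90 min. The opioid precursor gene pdyn (0.43 ± 0.031) and the neuropeptide Y gene npy (0.40 ± 0.069) rose, 2 of 26 neuropeptide genes, with 11 higher and 1 lower adjusted over the list alone. That list's camera adjusted p was 5.04e-05, with adjusted p = 0.223 with an estimated correlation, its medians were 0.22 and 0.16 on slides 1 and 2, and 6 rose with the replicate block. No member passed limma, over all genes or over the list alone, among 18 GABA signalling, 27 glutamate signalling and 16 voltage-gated channel genes. Those with the smallest p were the GABA receptor genes gabra4 (0.24 ± 0.10, adjusted p = 0.162) and gabrr2a (-0.17 ± 0.023, adjusted p = 0.232), the glutamate receptor gene gria2a (0.27 ± 0.038, adjusted p = 0.108) and transporter gene slc1a2a (0.29 ± 0.19, adjusted p = 0.159), and the channel genes kcnh6a (0.25 ± 0.12, adjusted p = 0.156) and scn8aa (0.22 ± 0.010, adjusted p = 0.165). The PTZ signal of gabrr2a was well above background on 2 of 4 arrays, and its ratio turned above 0 under median centring. The GABA and glutamate lists passed camera in the higher direction (both adjusted p = 0.0493), had an adjusted p = 0.360 and an adjusted p = 0.372 with an estimated correlation, and with the replicate block both gave an adjusted p = 0.0688. Their medians were 0.062 and 0.071 on slide 1, and 0.12 and 0.076 on slide 2. Relative to all genes, the GABA median went from 0.10 to 0.029 over the scalings tried, and the glutamate median stayed between 0.050 and 0.076. The channel list did not pass camera (adjusted p = 0.235).

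Of the lists of cell type markers, 4 passed camera with a preset correlation at 90 min and none with an estimated one. Of 32 photoreceptor and lens markers, 30 were above 0, with 1 that rose (pde6ga, 0.72 ± 0.27) and 1 that fell (otx5, -0.53 ± 0.17), or 6 and 1 over the list alone; camera gave an adjusted p = 2.08e-07, and adjusted p = 0.235 with an estimated correlation, with medians of 0.43 and 0.11 on slides 1 and 2, and 7 rose and 1 fell with the replicate block. Skin epithelium markers lay lower, with a camera adjusted p = 0.00236 (adjusted p = 0.223 with an estimated correlation) and medians of -0.14 and -0.14, although 0 of 24 rose and 0 fell (1 and 5 adjusted over the list alone). In that list itgb4 was at 0.55 ± 0.26 (adjusted p = 0.0531, and 0.00674 with the replicate block) and tp63 at -0.35 ± 0.034 (0.0540 and 0.0260), and with the block 1 rose and 1 fell. Blood and immune markers had medians of -0.12 and -0.10 and a camera adjusted p = 0.0205 (adjusted p = 0.235 with an estimated correlation), and 1 of 22 rose, mmp9, which the inflammatory list also holds (1 rose and 1 fell adjusted over the list alone). With the replicate block 1 rose and 4 fell. Liver, gut and pancreas markers had a camera adjusted p = 0.0145 in the lower direction (adjusted p = 0.585 with an estimated correlation), but a median of 0.10 on slide 1 against -0.35 on slide 2, and none of 37 passed over all genes or the list alone. There fabp1b.1 was at -0.46 ± 0.034 (adjusted p = 0.0691, and 0.0169 with the replicate block) and apoa4b.1 at -0.29 ± 0.060 (0.0859 and 0.0485), and 2 fell with the block. The neuronal marker inab fell (-0.39 ± 0.0021, adjusted p = 0.0419), 1 of 22 neuronal markers. Among 24 glial, 39 muscle and 19 housekeeping genes none passed over all genes, 2 glial markers rose and 1 fell adjusted over the list alone, and camera gave 0.144 for neurons, 0.175 for glia, 0.0747 for muscle (0.0405 with the replicate block) and 0.719 for housekeeping genes. Muscle markers had medians of 0.13 and 0.0055 on slides 1 and 2, and the median of the list turned to -0.088 relative to all genes under median centring. Values of the members with the smallest p were 0.50 ± 0.15 for cldnk (adjusted p = 0.0600, and 0.00561 with the replicate block), -0.48 ± 0.31 for sox2 (0.0924 and 0.0211), 0.32 ± 0.093 for ryr1b (0.211), 0.24 ± 0.19 for casq1a (0.297) and -0.30 ± 0.12 for tuba1b (0.121 and 0.0455). With the replicate block 2 rose and 1 fell among glial markers, 1 rose and 0 fell among muscle markers, and 0 rose and 1 fell among housekeeping genes. Reference genes were at -0.19 ± 0.027 for actb1 (adjusted p = 0.212) and -0.0088 ± 0.12 for eef1a1l1 (adjusted p = 0.971), and the signs of both turned under other settings.

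**Figure D1:**
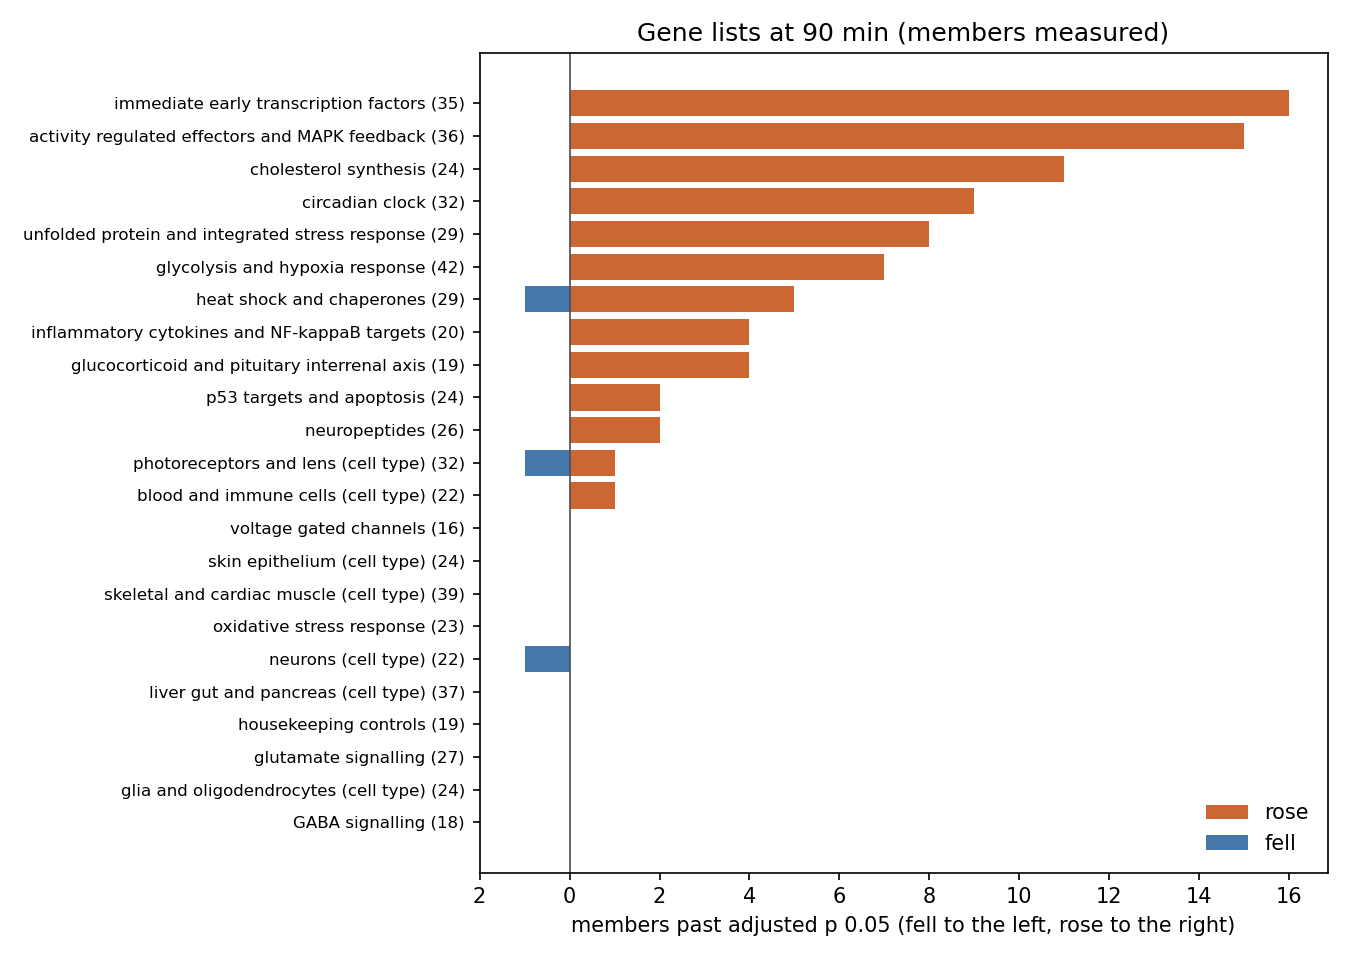
Members of the 23 gene lists past an adjusted p of 0.05 in limma at 90 min of PTZ, counted on the horizontal axis with genes that rose to the right of 0 and genes that fell to the left; the number of measured members is in brackets. Immediate early transcription factors had 16 of 35 rise, and GABA signalling 0 of 18.

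Each slide held the arrays of one replicate number at both durations. The 498 features that rose had medians of 0.66 and 0.68 on slides 1 and 2, and the 155 that fell had -0.59 and -0.47, all of them selected on the mean of both slides. With the slide, and so the replicate number, as a block, 1799 features passed (1090 up, 709 down), among them all 653. The error of that fit leaves out the spread between matings that both durations share. Median centring in place of loess called 665 with a different split, 391 up and 274 down. The count fell to 146 when the 90 min replicates were fitted alone. Leaving out either 30 min replicate repeats that fit, since the error then comes from the 90 min replicates alone. With the spread modelled as a trend over intensity, as planned, limma called 758. A trend over the log ratio, run by mistake, called 0 in limma, with 4265 at an unadjusted p under 0.05. That fit lets the size of a change set its own error.

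The 30 min comparison asked which of these transcripts had already moved. Of the genes named here, fosab (3.42 ± 1.43), npas4a (3.24 ± 0.87) and egr4 (2.76 ± 0.78) again had the highest ratios. No feature passed an adjusted p under 0.05 in limma, where 1249 had an unadjusted p under 0.05 and 13, all higher in PTZ, had an adjusted p under 0.1. The smallest adjusted p, 0.0580, was that of socs3a, a feedback inhibitor of cytokine signalling, at 2.14 ± 0.38. It was followed by junbb at 1.75 ± 0.11 (adjusted p = 0.0643), the cartilage matrix gene matn3a at 1.202 ± 0.071 (0.0643), the kinase gene pim2 at 0.88 ± 0.083 (0.0839) and tcima at 1.09 ± 0.075 (0.0983). Those of the other direction with the smallest p, none of them past the threshold, were rab11fip4a (-0.59 ± 0.095), ntan1 (-0.75 ± 0.36), akap17a (-0.35 ± 0.043), desi1a (-1.32 ± 0.23) and aplnra (-0.42 ± 0.10).

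With the slide, and so the replicate number, as a block, 86 features passed at 30 min, 80 higher and 6 lower in PTZ. Under that fit fosab, npas4a, egr4, socs3a, ier2a (1.90 ± 0.49), junbb, sik1 (1.73 ± 0.57), btg2 (1.59 ± 0.76), dusp1 (1.46 ± 0.51) and cmn (1.39 ± 0.25) were the 10 largest rises among genes with a standard symbol, with adjusted p from 2.27e-06 for fosab to 0.00243 for cmn. The genes desi1a (adjusted p = 0.00434) and ntan1 (adjusted p = 0.00542) fell under it. Other named genes that rose under it were matn3a, pim2, tcima, igfbp1a, jdp2b, gadd45ba, cisha, ptgs2b, hspb9, chac1, sgk1, socs1a and atf3, with adjusted p up to 0.0444 for atf3. Names were taken from this fit only after the unblocked result had been seen. Of the 80 features, 65 were also among the 1090 that rose at 90 min in the blocked fit, and 4 of the 6 were among the 709 that fell. Independent lists would share 3.64 and 0.178, values that leave out the slide and the spread estimate per feature, which both contrasts have in common. Fitting the 30 min replicates alone called 91 features. Leaving out either 90 min replicate repeats that fit, since the error then comes from the 30 min replicates alone. With duplicateCorrelation over 8 arrays 66 were called, and with the remaining fits from 0 to 134, apart from a fit that crossed the dye swaps and added the block (1620).

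Among the gene lists at 30 min, no member passed over all genes in limma, and 4 lists stood above other genes in camera with a preset correlation. Immediate early transcription factors had 31 of 35 members above 0, 14 past the threshold adjusted over the list alone and 11 with the replicate block (camera adjusted p = 4.82e-15, adjusted p = 0.675 with an estimated correlation). Activity-regulated effectors had 31 of 36 above 0, 10 over the list alone and 8 with the block (camera adjusted p = 3.61e-11, adjusted p = 0.768 with an estimated correlation). Inflammatory and NF-kappaB targets had 17 of 20 above 0, 5 over the list alone and 3 with the block (camera adjusted p = 2.06e-06, adjusted p = 0.675 with an estimated correlation). Skeletal and cardiac muscle markers had 31 of 39 above 0 and 0 past the threshold over the list alone (camera adjusted p = 0.00250, adjusted p = 0.675 with an estimated correlation). In that order the medians were 0.21, 0.19, 0.17 and 0.093 on slide 1, and 0.30, 0.26, 0.16 and 0.069 on slide 2. The glucocorticoid list passed camera with the replicate block alone (adjusted p = 0.0167 against 0.0566). Adjusted over their lists alone, 2 unfolded protein response genes, 2 glucocorticoid axis genes and 1 heat shock gene also passed. With the replicate block 2 glucocorticoid axis genes rose, and 1 gene each of the heat shock, unfolded protein and glycolysis lists. Cholesterol synthesis genes had a median of -0.012 and 0 of 24 past either threshold (camera adjusted p = 0.763), and clock genes a median of 0.044 (camera adjusted p = 0.179). Of the lists that passed no test at 30 min, cholesterol synthesis, p53 targets and liver markers had a median, mean and camera direction of differing sign.

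**Figure D2:**
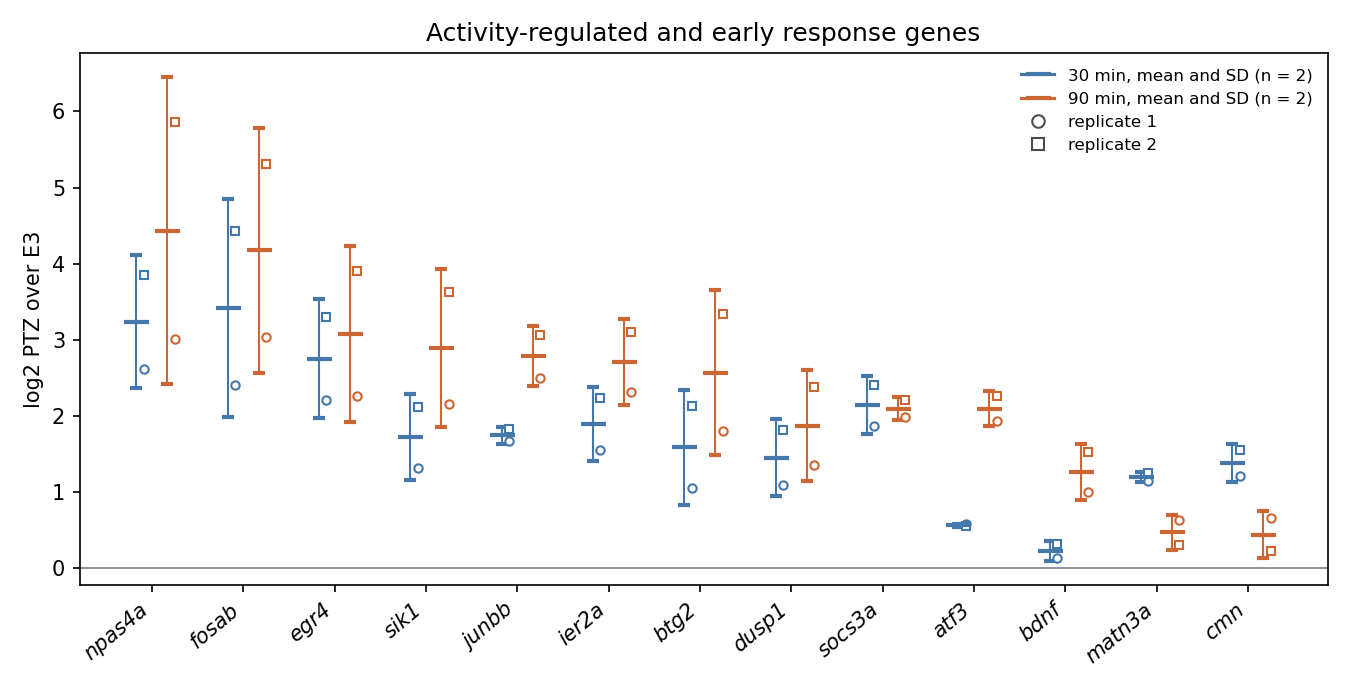
Log2 ratio of PTZ over E3 (vertical axis) for 13 genes at 30 and 90 min, with each replicate as a symbol and the mean and SD (n = 2) as a bar. Replicate 2 lies above replicate 1 in fosab and npas4a at both durations, while socs3a has a mean of 4.42-fold at 30 min and 4.29-fold at 90 min.

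Whether the response differed between the durations was tested as the 90 min ratio minus the 30 min ratio. Among genes with a symbol, the highest gains belonged to cyp24a1, which went from 0.46 ± 0.13 to 2.86 ± 0.24, rrad, a small GTPase gene, from 0.093 ± 0.085 to 1.86 ± 0.24, and mmp9, from 0.18 ± 0.24 to 1.87 ± 0.17. Without a block no feature passed in limma, 1918 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0867, that of cyp24a1. With the slide, and so the replicate number, as a block, 198 features passed, 158 with a higher and 40 with a lower ratio at 90 min. In the blocked fit the largest gains were cyp24a1, rrad, mmp9, the xenobiotic-metabolizing gene cyp1a (0.44 ± 0.28 to 2.00 ± 0.44), igfbp1a (1.09 ± 0.32 to 2.64 ± 0.52) and atf3 (0.57 ± 0.021 to 2.099 ± 0.23), with adjusted p from 0.000626 for cyp24a1 to 0.00253 for atf3. Its largest losses included the hatching enzyme genes he1.1 (0.12 ± 0.66 to -1.78 ± 1.24) and he1.2 (0.14 ± 0.69 to -1.68 ± 1.09), the cathepsin gene ctslb (0.32 ± 1.05 to -1.47 ± 1.01), MGC174155 (0.30 ± 1.02 to -1.44 ± 0.96), serpinh1b and foxc1a. The adjusted p without the block was 0.498 for he1.1 and 0.556 for ctslb. At 90 min itself he1.1, he1.2, ctslb, MGC174155, ntan1, acaa1 and matn3a passed with the block and not without it, with adjusted p up to 0.0173 for matn3a. In all 46 of 93 named genes passed for the difference in the blocked fit, with adjusted p up to 0.0482 for mcl1a. Genes with the smallest p without the block, none past the threshold, also included bhlhe41 (0.101), pax9 (0.131), foxd2 (0.184) and acaa1 (0.195), the last going from 0.42 ± 0.024 to -0.42 ± 0.17. Fits that left out a 90 min replicate called 182 and 429, those that left out a 30 min replicate 0, and the remaining fits from 0 to 292, apart from a fit that crossed the dye swaps and added the block (3326).

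Cholesterol synthesis had the largest median difference and the smallest camera p of the 23 lists: 23 of 24 members had a higher ratio at 90 min, 18 passed adjusted over the list alone, 0 over all genes and 7 with the replicate block. Its median difference was 0.51, with a camera adjusted p = 1.85e-22 and adjusted p = 0.193 with an estimated correlation. Examples were msmo1 (0.22 ± 0.050 to 1.61 ± 0.35) and ebp (0.015 ± 0.042 to 1.15 ± 0.23), with differences at adjusted p = 0.00597 and 0.00688 in the blocked fit. The clock list had a median difference of 0.26, 8 members past the threshold over the list alone and 5 with the block (camera adjusted p = 3.17e-10, adjusted p = 0.193 with an estimated correlation). Immediate early factors gained 0.42 in the median, with 6 past over the list alone and 9 with the block (camera adjusted p = 5.21e-10, adjusted p = 0.230 with an estimated correlation). Effectors gained 0.36, with 9 and 9 (camera adjusted p = 5.02e-10, adjusted p = 0.419 with an estimated correlation). With the block 3 unfolded protein response genes, 3 glycolysis and hypoxia genes and 3 heat shock genes had a higher ratio at 90 min, as did 2 inflammatory genes, and 1 gene each of the glucocorticoid, p53, photoreceptor and blood lists; 1 heat shock gene had a lower one. Over their lists alone, 7, 4 and 4 of the first 3 of these lists, and 3 glucocorticoid axis genes, passed as higher. In total 14 of 23 lists passed camera with a preset correlation and 0 with an estimated one, and 15 passed with the replicate block, which added liver, gut and pancreas markers (adjusted p = 0.0415). The median (0.0014) and mean (-0.018) of muscle markers, which passed no test, differed in sign.

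Across the 23929 features, the mean ratios at 30 and 90 min correlated with a Pearson r of 0.54 and a Spearman rho of 0.36, without a p-value since genes are not independent. No E3 larvae were shared between the durations. Replicates on one slide correlated across durations at 0.48 on slide 1 and 0.44 on slide 2, and those on different slides at 0.36 and 0.24. Of the 498 features that rose at 90 min, 467 (93.8%) had a ratio above 0 at 30 min, with medians of 0.19 and 0.17 on slides 1 and 2. Of the 155 that fell, 137 (88.4%) lay below 0 at 30 min.

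**Figure D3:**
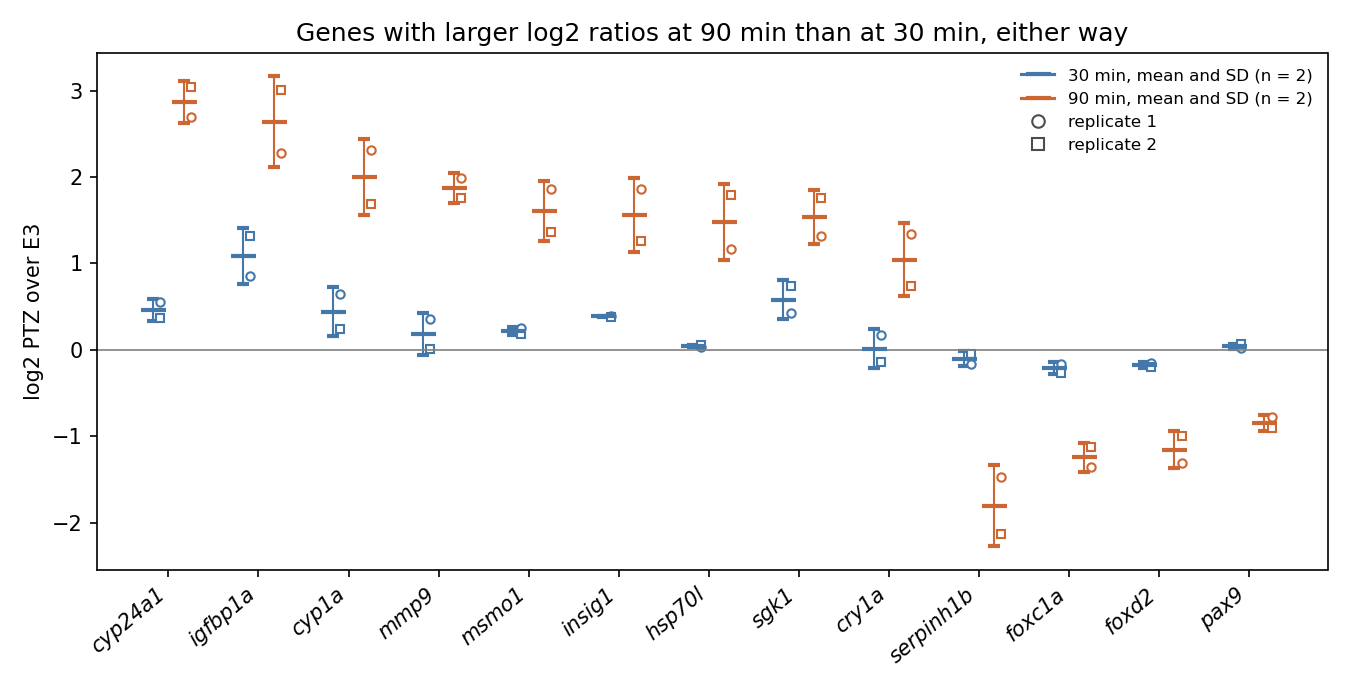
Log2 ratio of PTZ over E3 (vertical axis) for 13 genes at 30 and 90 min, with each replicate as a symbol and the mean and SD (n = 2) as a bar. The ratio of cyp24a1 is 0.46 at 30 min and 2.86 at 90 min, and that of serpinh1b -0.10 and -1.80.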

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

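No test reported here was chosen only after its result was seen. The shift of 14 gene lists differed between 90 and 30 min in camera with a preset correlation, and that of none with an estimated correlation. The median differences, 90 min minus 30 min, were 0.51 for cholesterol synthesis, 0.42 for immediate early transcription factors, 0.36 for activity-regulated effectors, 0.28 for photoreceptor and lens markers, 0.26 for the circadian clock, 0.26 for the glucocorticoid axis and 0.23 for neuropeptides. From 30 to 90 min the glucocorticoid median went from -0.014 to 0.35 on slide 1 but from 0.14 to 0.12 on slide 2, while the medians of the other lists in this group rose on both slides. Smaller gains were 0.12 for inflammatory targets, 0.11 for glycolysis and hypoxia, 0.086 for p53 targets, 0.053 for the unfolded protein response and 0.052 for glutamate signalling. Relative to all genes, the lowest gains over the scalings tried were 0.0027 for the unfolded protein response, 0.014 for p53 targets and 0.031 for glycolysis. They were 0.11 for inflammatory targets and 0.061 for glutamate signalling. On slide 2 the unfolded protein median went from 0.047 at 30 min to 0.034 at 90 min. Blood and immune markers (-0.18) and skin markers (-0.13) went the other way. From 30 to 90 min the blood median went from -0.11 to -0.12 on slide 1 and from 0.050 to -0.099 on slide 2. The skin median went from -0.016 to -0.14 on slide 1 and from 0.018 to -0.14 on slide 2.

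A higher immediate early ratio at 90 than at 30 min could arise if E3 larvae had themselves responded to the transfer and that response was still present at 30 min. Over the 16 immediate early genes that rose at 90 min, the median level of E3 larvae at 30 min minus that at 90 min was 0.010 (standard error 0.053, above 0 in 9 of 16) on slide 1 and 0.031 (standard error 0.11, 9 of 16) on slide 2. The PTZ over E3 ratio of the same genes gained 0.73 and 0.91, and the E3 values lie below that gain on both slides. For these 16 genes, this argues against a decaying E3 response as the source of the whole gain. They were selected for a rise at 90 min, which favours a larger gain. Over all 35 measured members the median ratio went from 0.21 to 0.63 on slide 1 and from 0.30 to 0.60 on slide 2. E3 levels were not compared over those 35. The standard errors are over genes, which are not independent. Each slide holds 1 E3 pool per duration, so the spread between pools is not in them. On slide 2 the standard error is larger than 10% of the gain of the 16 genes, the bound written beforehand, so a share of the gain stays open. The duration of PTZ itself remains open as an untested biological explanation.

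Single arrays stood apart from the other 3 of their duration in 5 of 186 groups of 4 arrays. Among independent arrays chance alone marks about 1 in 20 groups, here 9.3. The arrays of one replicate share a slide and a mating, so that count is only a rough guide. The first-orientation array of replicate 1 gave pim2 at 90 min 1.36, against 1.60 to 1.63 on the other arrays, and socs1a at 30 min 0.19, against 0.67 to 0.71 on the other arrays. That of replicate 2 gave foxc1a at 90 min -0.82, against -1.44 to -1.34 on the other arrays, and bhlhe40 at 30 min 0.20, against 0.33 to 0.35 on the other arrays. The dye-swap array of replicate 2 gave kcnh6a at 90 min 0.50, against 0.16 to 0.18 on the other arrays.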

How the results depend on the processing

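Fits with the trend over the log ratio, the replicate block with crossed dye swaps and the replicate block with the strict filter were chosen after seeing the data, the first having been run by mistake for the planned trend over intensity. Counts of called features follow as 30 min, 90 min and difference, against 0, 653 and 0. The replicate block gave 86, 1799 and 198, added calls for 25, 15 and 46 of 93 named genes, removed 0, and changed no other list call than those given with the results. It gave 62, 1471 and 163 with both channels well above background throughout, and 1620, 7899 and 3326 with dye swaps crossed. In the crossed fits each averaged pair mixes both matings, so the spread between matings is not in their error; without the block, crossing gave 134, 2293 and 292. Arrays taken as independent gave 74, 2319 and 266 and duplicateCorrelation 66, 1830 and 160, where the error includes the spread between arrays of one replicate. In both, the 8 arrays set the degrees of freedom, although the 2 arrays of a replicate hold the same RNA pair. The first counts them as separate replicates, and duplicateCorrelation allowed a correlation of 0.12 between them. Each duration alone gave 91 and 146. A trend over intensity with robust fitting gave 5, 758 and 1, and over the log ratio 0, 0 and 0. The trend over the log ratio lets the size of a change set its own error. Leaving out one replicate gave 0 to 91, 146 to 2128 and 0 to 429, the lone remaining replicate being assumed to vary like the others. Median centring gave 17, 665 and 4, the deposited values 20, 662 and 67, Feature Extraction ratios 2, 460 and 0, no background subtraction 0, 596 and 2, no filter 6, 665 and 1, the mean of probes 5, 621 and 0 and every probe alone 14, 842 and 0. First-orientation arrays alone gave 4, 513 and 3, and dye-swap arrays alone 8, 702 and 0. In a single orientation the gene-specific dye effect does not cancel. Similar counts at 90 min did not mean the same features. Of the 653, 353 were among the 513 and 440 among the 702. Median centring shared 469 of its 665, the deposited values 517 of 662 and Feature Extraction ratios 399 of 460. At 90 min 131 passed with at least a 2-fold change and 123 at an adjusted p under 0.01. Where no construction is named, the cause was not tested.

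Camera passed 4, 16 and 14 lists, 7 at 30 min with median centring, 7 with the deposited values and 7 with dye-swap arrays alone, and 0, 0 and 0 with an estimated correlation. Left-out replicates gave 4, 12 to 15 and 12 to 15 lists. The correlation of 30 and 90 min responses was 0.56 over strictly filtered genes, against 0.54. Of 2828 values of named genes under alternatives, 2249 kept direction and side of the threshold, 186 lost and 385 gained the call, and 8 turned sign, none of them a called value. These were gabrr2a at 90 min (0.028 with median centring), actb1 with dye-swap arrays alone (0.23 at 30 and 0.074 at 90 min), and eef1a1l1 with dye-swap arrays alone (0.18 and 0.19), with the mean of its probes (0.0059 at 90 min), without 30 min replicate 2 (0.038) and without 90 min replicate 1 (0.078). Leaving out one replicate moved eef1a1l1 from -0.18 to 0.038 at 30 min and from -0.10 to 0.078 at 90 min. Of 57 named genes called at 90 min, 32 kept the call with that duration fitted alone, 41 with Feature Extraction ratios and all 57 with the replicate block. Signal over background limits dim genes such as egr1.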

Other observations

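The tests of gene families, of features that rose at 30 min, and of large ratios on slide 1 were chosen only after the results were seen. Families of developmental transcription factors were chosen after the falls of foxc1a, foxd2, foxa2 and pax9 had been seen, and most of their members did not pass at 90 min. Camera with a preset correlation, adjusted over 8 families, put hox (1.53e-11), sox (5.06e-07), forkhead and pax genes (both 2.46e-05) below other genes, values that for forkhead and pax partly restate those falls. With the genes already named left out, it gave 0.00134 for 42 forkhead, 0.000528 for 10 pax and 1.87e-06 for 20 sox genes, and none of these calls held with an estimated correlation (adjusted p = 0.109 for hox, and for the other 3 families 0.634 with all genes and 0.653 without those named). Of 46 measured hox genes, 40 had a ratio below 0, with a median of -0.20 against 0.022 at 30 min, and 4 fell (hoxa2b, -0.70 ± 0.28; hoxb2a, -0.52 ± 0.19; hoxb6b, -0.37 ± 0.034; hoxc4a, -0.66 ± 0.10). Of 45 forkhead genes 9 fell and 1 rose (foxq1a, 1.59 ± 0.45, E3 signal well above background on 3 of 4 arrays), with foxc1b at -0.70 ± 0.031 and foxd1 at -0.62 ± 0.28. The median was -0.35 over 21 sox genes, with sox21a (-0.49 ± 0.064) the 1 that fell, and -0.45 over 11 pax genes, with pax9 and pax1a (-0.72 ± 0.17, PTZ signal well above background on 3 of 4 arrays) falling. With the replicate block 11 hox, 11 forkhead, 10 sox and 7 pax genes fell, and 3 forkhead and 1 sox gene rose. Over the scalings tried, the medians relative to all genes stayed below 0 in these 4 families. No gene passed in limma among 21 tubulin, 23 collagen and 84 ribosomal protein genes, where 2, 1 and 3 had an unadjusted p under 0.05 and 1 tubulin gene fell and 1 ribosomal protein gene rose with the block. Ribosomal protein genes passed camera in the higher direction (adjusted p = 0.0283, and 0.653 with an estimated correlation), 20 of 84 being below 0, but their median relative to all genes went from 0.039 to -0.11 over the scalings tried. Of 11 histone genes 1 rose (h2ax1, 0.55 ± 0.22).

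Of the 80 features that rose at 30 min with the replicate block, 30 had a higher and 3 a lower ratio at 90 min past the threshold for the difference in that fit. These features were selected for a high ratio at 30 min, which by itself favours lower values at 90 min, so the 3 are given as values. Of these, 1 has a standard symbol, the cartilage collagen gene col9a1b (1.15 ± 0.21 and 0.25 ± 0.24, adjusted p of the difference 0.0443 in the blocked limma fit), named after its values were seen. The ratio of cmn was 1.39 ± 0.25 at 30 min and 0.44 ± 0.31 at 90 min (0.0614 in that fit), and that of matn3a 1.202 ± 0.071 and 0.47 ± 0.23 (0.0511). The ratio of socs3a was 4.42-fold and 4.29-fold (0.950).

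Several immediate early genes had larger ratios in replicate 2 than in replicate 1 at 90 min: 5.31 against 3.04 in fosab and 5.86 against 3.01 in npas4a, and over the 16 that rose replicate 2 minus replicate 1 had a median of 0.44 (standard error 0.30, above 0 in 11). Standard errors here are over genes, which are not independent. The other 112 features that rose at least 2-fold had a median of 0.33 (standard error 0.057, above 0 in 82), as compression of large ratios on slide 1 would need. The 7 features that fell at least 2-fold did not decide this, with a median of 0.24 (standard error 0.19, 4 further from 0 on slide 1, but serpinh1b at -1.47 on slide 1 and -2.14 on slide 2). Of the 22 with such a mean fall, called or not, 18 fell further on slide 1 (median 1.23, standard error 0.31), but they include the hatching genes. The 155 called falls also had a median further from 0 on slide 1 (-0.59 against -0.47). Compression on slide 1 thus stays undecided. The rises leaned towards it, the wider sets of falls leaned the opposite way, and the 7 features did not decide. The level of the 16 genes in E3 larvae was also higher in replicate 1, by a median of 0.52 (standard error 0.23, 12 of 16), so a higher baseline in that mating is a second candidate explanation. That level is the denominator of the same ratios, so the gap in E3 levels and the gap in ratios are not independent. For fosab the E3 level was 13.13 against 11.45 at 90 min and 13.33 against 11.47 at 30 min. Slide, scan and mating coincide in this design and cannot be told apart, and a difference between matings stays open as untested.

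The hatching enzyme genes he1.1 and he1.2 and the cathepsin gene ctslb had large 90 min ratios with a wide spread (-1.78 ± 1.24, -1.68 ± 1.09 and -1.47 ± 1.01), and did not pass without the block. A candidate explanation is that pools of 20 larvae differed in how many still carried hatching gland cells. Over 6 hatching gland markers written down before the test, the mean level differed between E3 pools of the 2 replicates by an SD of 0.14, against a mean ratio of -0.88 ± 0.66 (SD, n = 2) at 90 min, below the bound set beforehand. That mean level covers markers whose E3 levels went opposite ways at 90 min, with he1.2 at 12.94 and 13.24 in replicates 1 and 2 but ctslb higher in replicate 1. PTZ pools were not compared, although the PTZ level of he1.2 was 12.74 and 13.85 at 30 min and 10.49 and 12.33 at 90 min. The test therefore could not decide this explanation. The list's mean ratio was -0.21 and 0.35 at 30 min and -1.35 and -0.41 at 90 min on slides 1 and 2, while he1.3 (-0.020 ± 0.15), cd63 (0.055 ± 0.0014) and klf17 (-0.40 ± 0.48) lay nearer 0. The E3 level of ctslb was 14.72 and 13.82 in replicates 1 and 2 at 30 min and 14.75 and 13.66 at 90 min, a gap that recurs with the replicate number, 4 E3 pools give a coarse estimate, and an effect of the longer exposure stays open as untested.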
